A study of Arabidopsis thaliana with 1664 samples.

How the data were processed

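RNA was measured in single nuclei sorted from ground Arabidopsis thaliana seeds of reciprocal Col/Cvi and Col/Ler crosses, 2 to 5 days after pollination (DAP). Libraries were made by a reduced-volume Smart-seq2 procedure in 96-well plates, per the labels' protocols. Nuclei came from the 3C and 6C peaks of DNA content, and at 2 DAP from the 3C and 4C peaks. Trim Galore 0.4.1, STAR 2.7.1a, Picard and HTSeq 0.9.1 and the build TAIR10 are named in the submitters' processing notes. The role of each tool, the handling of strand and the rule that assigned reads to a parent are not given in the sources used here. The authors deposited, per library, whole-number read counts per gene and, beside them, counts of reads assigned to each parental strain. They also deposited maternal and paternal score values per gene, whole numbers titled as normalized, whose scaling is not given in the sources used here. A deposited table of CPM was not used here, since the counts hold the same reads.

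The design fixed before the data were examined assumed that only normalized parental values existed. Since raw parental counts were there for every nucleus, these were used, and the normalized values became an alternative. They cover 748 nuclei, of which 746 were among the endosperm-like nuclei defined here. Loci were named from a TAIR10.1 reference annotation used only for names. Of 35366 loci 34879 matched and 10664 had a symbol. Counts of near-identical genes, such as CDC20.1 and CDC20.2, VIM1 and VIM5, 3xHMG-box1 and 3xHMG-box2, or the LHCB1 copies, are uncertain, since the counting could split or drop shared reads. The same holds for overlapping and antisense genes.

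A library passed with at least 1500 genes detected and at least 1000 genes at 5 or more reads, the filter given in the series text. It left 1430 of 1549 single nuclei, slightly fewer than the series text counts. The total count of the passing nuclei ranged from 17874 to 619535 with a median of 152118, and 18.6% of their reads carried a parental assignment. Reads had no molecular identifiers, so intervals and floors cover counting error only. Doublets were not called, because wells of 2 nuclei were made on purpose and labelled.

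Nuclei were clustered in scanpy 1.11.5 from log counts per 10000, 2000 variable genes chosen and centred within cross, 30 principal components and 15 neighbours, at Leiden resolution 1. Clusters were named from marker lists fixed before the data were examined. A marker counted when it was found in at least 10% of the nuclei of a cluster and at least 1.5-fold higher there, with 10 CPM added to both means. A cluster was seed coat-like with at least 3 such seed coat markers, and more of them than of endosperm or embryo markers, over all other nuclei. It was endosperm-like with at least 3 endosperm markers over the seed coat-like nuclei, and more of them than of seed coat or embryo markers. A cluster with 3 or more of 6 pollen genes among its 20 leading genes stayed unnamed. This naming rule and the 6 pollen genes were set after a first clustering and after maternal shares had been seen. Comparing each cluster with all others alone, and merging clusters by their centroids, were tried before it. Endosperm-like clusters 3, 5, 7, 9, 11 and 16 have no endosperm marker among their 10 leading genes, and in cluster 4 an endosperm and an embryo marker, ALE1 and WOX8, both lead.

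The replicate was the plate within a cross, with day and peak where these were compared, and units under 5 nuclei were left out. The labels name no plants or seed batches. P-values therefore measure the spread between plates, which may be technical. Counts were summed per unit. They were tested with edgeR 4.0.16 by the quasi-likelihood test with TMM scaling, the filterByExpr filter and Benjamini-Hochberg adjustment at 0.05. Standard errors are the log2 fold change over the square root of F. Gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01, and with fry. Folds against a group with no read were computed from the summed counts of each group over its summed effective library size, with a floor of 3 counts for the group without reads. All other folds are fitted by the model. Either can differ from the ratio of the mean CPM printed beside it, most of all for genes with units near 0. The 3C and 6C units of a plate and cross share a batch label, which pairs them. The deviations of the 15 pairs correlated between -0.053 and 0.159.

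Parental ratios were log2 of maternal over paternal reads with 0.5 added to both, for genes with at least 10 parental reads in at least 4 units of each direction. They were tested in limma 3.58.1 against 2 maternal to 1 paternal, with weights N/(N + 20) from the number of reads N. A call needed an adjusted p under 0.05, a mean departure of at least 1 on the log2 scale and the same direction in both crosses. Shares were compared by exact sign-flip and permutation tests, or with 100000 draws, all of them two-sided.

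Named genes followed a rule fixed before the data were examined. It takes the 10 largest rises and falls among genes past the threshold with a mean log2 CPM of at least 3 and a symbol, and up to 3 members per list. For parental ratios it takes the 10 smallest adjusted p per direction and all measured members of both imprinted lists. Where the text names a gene outside this rule, it says so.

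The count tests and the ratio test were tried on simulated data. For the count tests 200 genes were changed. With 16-fold changes edgeR recovered 85% of genes for the 3C and 6C comparison and 81% for Col x Cvi against Cvi x Col. For Col x Ler against Ler x Col it recovered 21%, for 5 against 3 DAP 15% in Col/Cvi and 2% in Col/Ler, and for the wash 73%. With 4-fold changes the recovery was 34%, 48%, 0%, 0%, 0% and 44% in the same order. limma recovered 94.0% of 84 genes with 4-fold departures from the parental ratio, and 10.2% of its simulated calls were false, above the nominal 5%. There the unchanged genes lay at exactly 2 maternal to 1 paternal, with the same overdispersion for all genes. The median measured gene was 77.8% maternal, so the share of false calls among the measured ones is not given by this simulation.

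Alternatives fixed beforehand were DESeq2 1.42.0, RLE factors, no count filter, other clusterings, larger units, plate blocks, each unit left out and other limits for parental ratios. Alternatives added after the data had been seen were the normalized parental tables, leaving out cluster 9, adding the cluster led by pollen genes, plate as a block for the days in Col/Cvi, units of any size, the micropylar cluster, and genes at least 2 times as abundant in endosperm-like nuclei. Wells of 2 nuclei and control wells entered only the comparisons that name them.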

Results

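The series set out to profile gene expression and parental contribution in individual endosperm nuclei of Arabidopsis thaliana. Endosperm, the seed tissue that feeds the embryo, holds 2 maternal genomes and 1 paternal genome, while the seed coat around it is purely maternal. Read counts were collected from 1549 wells of 1 nucleus, 51 wells of 2 nuclei, 38 wells without a nucleus and 26 water wells. Crosses are written mother first. At 4 DAP the passing single nuclei numbered 547 from Col x Cvi and 548 from Cvi x Col, on 8 plates each, and 37 from Col x Ler and 30 from Ler x Col, on 2 plates each. Smaller sets came from 2, 3 and 5 DAP. Passing nuclei had a median total count of 152118 and a median of 3282 genes detected. The control wells, 0 of which passed, had a median total count of 19.5 (range 0 to 6666) and a median of 9 genes (range 0 to 788).

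Wells with 2 nuclei checked the sorting. In 3C wells they held 4416 ± 812 genes (SD, n = 27 plate, cross and day units) against 2844 ± 366 in wells of 1 nucleus. The difference was positive in 25 of 27 units (sign-flip permutation test with 100000 draws, p = 1e-05, the smallest it can give). Total counts were 1.55-fold higher (p = 0.00032 in the same test, higher in 22 units).

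Nuclei fell into 18 clusters, of which 9 were endosperm-like (937 nuclei), 8 were seed coat-like (451 nuclei) and 1 stayed unnamed (42 nuclei). As a mean over nuclei FWA, an imprinted homeobox gene of the endosperm, stood at 233 CPM in endosperm-like and 34.4 CPM in seed coat-like nuclei. ZOU, a regulator of endosperm breakdown, stood at 69.8 and 10.5 CPM. In the other direction SHP1, an ovule and seed coat MADS gene, stood at 702 CPM in seed coat-like and 67.8 CPM in endosperm-like nuclei, and MYB5 at 548 and 39.8 CPM. BAN, a proanthocyanidin enzyme of the inner seed coat, was found in 83.1% of seed coat-like and in 82.6% of endosperm-like nuclei, at 1067 and 503 CPM. Clusters are defined by such genes, so these levels describe the classes and are not tests. Cluster 4 held 4 micropylar markers and cluster 16 held 3 chalazal markers. An embryo-like cluster of 9 or 10 nuclei separated only at resolution 0.5, resolution 2 or without centring.

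**Figure D1:**
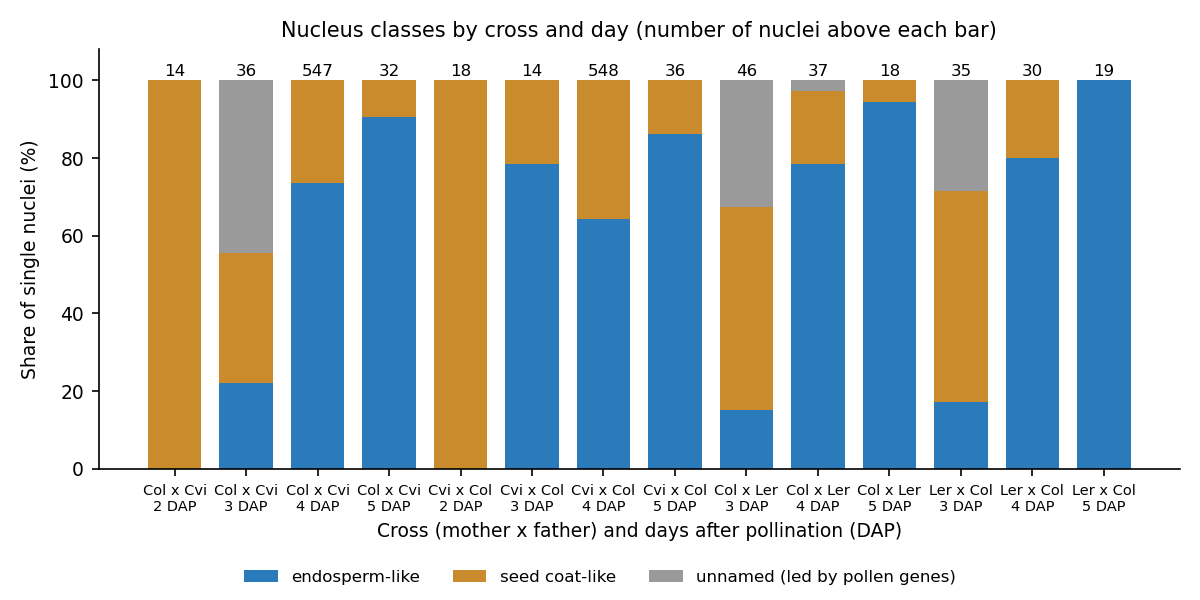
Share of passing single nuclei in each class (vertical axis, percent) by cross and day after pollination (horizontal axis), with the number of nuclei above each bar. All 32 nuclei of 2 DAP were seed coat-like, and endosperm-like nuclei made up between 64.4% and 80% at 4 DAP.

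All 32 nuclei of 2 DAP were seed coat-like, with a maternal share of 98.8% of assigned reads (range 97.1% to 99.6%), so no endosperm was measured at that day. The unnamed cluster was led by pollen genes such as VGD1, a pollen tube pectin methylesterase, and 41 of its 42 nuclei were of 3 DAP by label. Its median maternal share was 75.8%, and it held FWA at 446 CPM and AGL62, an endosperm MADS gene, at 47.0 CPM. It was left out of the comparisons below.

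The parental share of reads separated the classes at 4 DAP in Col/Cvi. The rule that named the classes was set after maternal shares had been seen, so this is not an independent check of them. Endosperm-like nuclei had a maternal share of 74.6% ± 2.06 (SD, n = 16 plate and cross units), above the 66.7% of 2 in 3 genomes in 16 of 16 units (exact sign-flip test, p = 3.05e-05). Seed coat-like nuclei had 94.97% ± 2.02 (n = 15), below 100%. With Col as the mother the endosperm-like share was 75.95% ± 1.75 (n = 8) and with Cvi 73.2% ± 1.33 (n = 8), a difference of 2.73 points (exact permutation test, p = 0.00466). Across endosperm-like clusters the median over nuclei lay between 72.9% in cluster 16 and 76.1% in cluster 3, apart from 81.6% in cluster 9, which has 26 nuclei at this day. Washed plates had 75.6% ± 1.89 (n = 4) and unwashed plates 74.2% ± 2.07 (n = 12, exact permutation test, p = 0.248). Seed coat-like nuclei had 93.6% ± 1.53 on washed (n = 4) and 95.5% ± 2.01 on unwashed plates (n = 11, exact permutation test, p = 0.119). With clusters at resolution 0.5, at resolution 2 or without centring, their share was lower on washed plates by 2.07, 2.32 and 2.15 points (p = 0.00147, 0.000999 and 0.00220 in the same test).

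**Figure D2:**
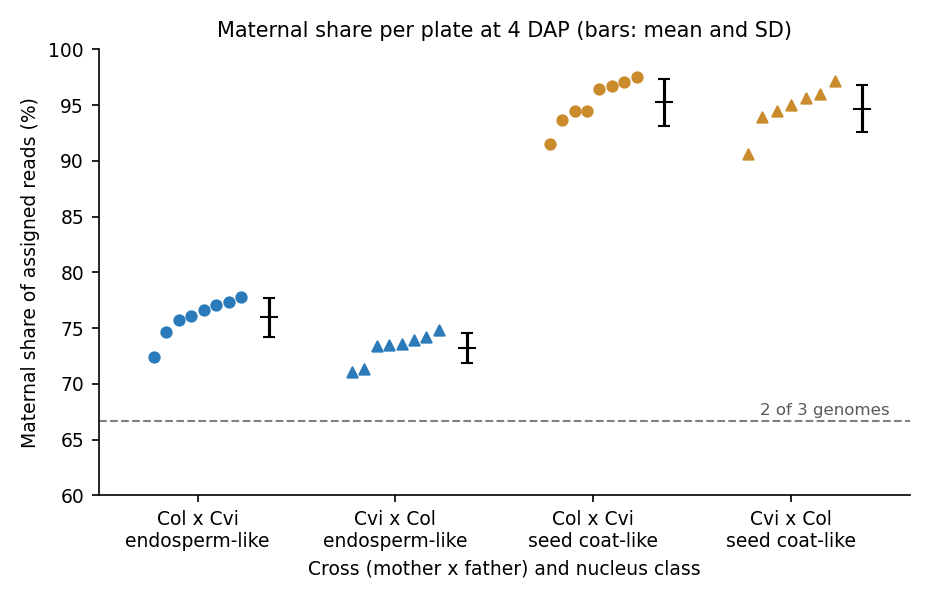
Maternal share of parentally assigned reads (vertical axis, percent, starting at 60) in each plate at 4 DAP, by cross and class (horizontal axis), with mean and SD beside the points. Endosperm-like units lie between 71.1% and 77.8%, above the dashed line at 2 of 3 genomes, and seed coat-like units between 90.6% and 97.5%.

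Endosperm-like nuclei made up 62.8% ± 13.6 of 3C nuclei and 80.8% ± 12.8 of 6C nuclei (SD, n = 16 units), higher in 6C in 12 of 16 units (exact sign-flip test, p = 0.00842). The gain was 31.7 points in Cvi x Col and 4.12 points in Col x Cvi, and the crosses differed (exact permutation test, p = 0.0120). All 8 units of Cvi x Col were higher in 6C, but 4 of 8 units of Col x Cvi were lower (plates 8, 14, 20 and 21).

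Endosperm-like 6C nuclei held more transcripts of cell division genes than 3C nuclei, and fewer of DNA replication genes. ATK1, a spindle kinesin, stood at 223 ± 132 CPM (SD, n = 15 units) in 6C and 29.4 ± 50.6 CPM (n = 16) in 3C nuclei, 7.80-fold higher (log2 2.96 ± 0.60 SE, adjusted p = 0.00503). POK1 and KINESIN-12B, kinesins of the phragmoplast, stood at 76.3 ± 105 and 83.8 ± 64.7 CPM in 6C and 9.19 ± 24.3 and 17.5 ± 39.2 CPM in 3C nuclei. MCM7, a subunit of the replicative helicase, stood at 74.1 ± 43.2 CPM in 6C and 305 ± 109 CPM in 3C nuclei, 4.16-fold lower (log2 -2.06 ± 0.31 SE, adjusted p = 0.000126). ATXR6, a histone methyltransferase of replicating chromatin, was 23.4-fold lower. The peaks also held different clusters of the class, since 3.39% of the nuclei of cluster 3 and 2.33% of cluster 11 came from 6C, against 98.1% of cluster 7 and 83.3% of cluster 16.

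In the edgeR test 116 of 16489 genes differed between the peaks, 74 higher and 42 lower in 6C. The G2 and mitosis list rose as a group (camera adjusted p = 2.04e-19, and adjusted p = 0.00483 with an estimated correlation). TOPII, CDKB2;2 and CYCB1;2 were the 3 of its 24 measured genes that rose, with 14 adjusted over the list alone, and its median log2 fold change was 1.71. The S phase list fell (camera adjusted p = 1.02e-45, and adjusted p = 9.33e-07 with an estimated correlation). 9 of its 18 measured genes fell, 14 adjusted over the list alone, with a median log2 fold change of -1.80. MCM5 (4.45-fold), MCM6 (7.02-fold), ETG1 (9.94-fold), BRCA1 (6.32-fold), BARD1 (7.99-fold) and BRCA2(IV) (6.01-fold) were also lower in 6C. MET1, which maintains DNA methylation after replication, was 4.57-fold lower. 3xHMG-box1 and 3xHMG-box2, proteins of mitotic chromosomes, were 6.17-fold and 5.37-fold higher. GRF13, iqd8 and BSK9 had the largest fitted rises, with 39.9 ± 46.0, 77.4 ± 79.8 and 44.6 ± 69.4 CPM in 6C and 2.75 ± 6.03, 5.78 ± 13.2 and 4.03 ± 7.04 CPM in 3C nuclei, though BSK9 was not past the threshold with plate and cross as a block.

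Of 13 measured core histone genes 0 fell over all genes (3 at an unadjusted p under 0.05) and 1 when adjusted over the list alone (camera adjusted p = 6.33e-06, and adjusted p = 0.0277 with an estimated correlation). The 7 measured paternally expressed imprinted genes had a camera adjusted p of 0.0453 in the direction of 6C, and adjusted p = 0.340 with an estimated correlation. The seed coat markers did not move with the peak (20 measured, camera adjusted p = 0.835). With plate and cross as a block 200 genes differed, 141 higher and 59 lower in 6C, of which 107 were among the 116. In that fit the S phase and G2 and mitosis lists kept adjusted p = 8.27e-06 and 0.00276 with an estimated correlation, and core histones had 0.142.

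**Figure D3:**
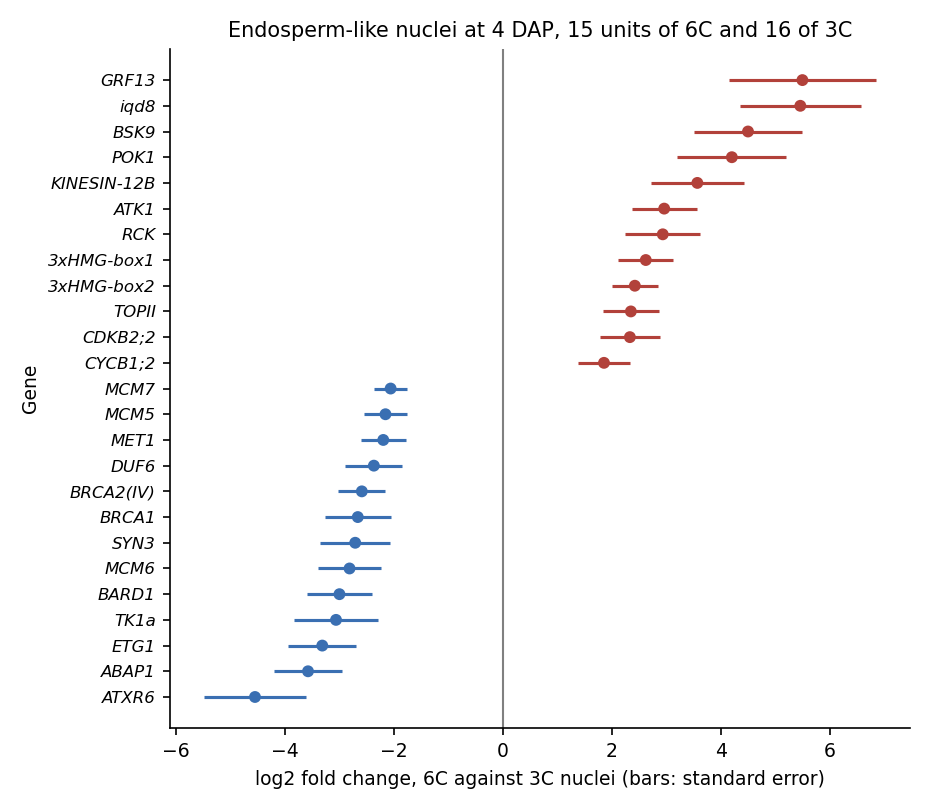
Log2 fold change of the named genes in 6C against 3C endosperm-like nuclei at 4 DAP (horizontal axis), with bars for the standard error over 15 and 16 units. Genes higher in 6C lie right of 0 and genes lower in 6C left of it, from ATXR6 at -4.55 to GRF13 at 5.50.

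Endosperm-like nuclei of the reciprocal Col/Cvi crosses differed widely at 4 DAP. KN, the syntaxin of cell plate formation, stood at 528 ± 89.5 CPM with a Col mother and 38.7 ± 26.3 CPM with a Cvi mother (SD, n = 8 units each), 13.6-fold higher (log2 3.76 ± 0.44 SE, adjusted p = 5.39e-06). CLF, a Polycomb histone methyltransferase, was 15.8-fold higher with a Col mother, and GA20OX3, an enzyme of gibberellin synthesis, was 95.6-fold higher. FWA stood at 79.4 ± 31.9 CPM with a Col mother and 478 ± 98.7 CPM with a Cvi mother, 6.04-fold lower with Col (log2 -2.59 ± 0.25 SE, adjusted p = 4.40e-07). HDG8, a further imprinted homeobox gene, was 11.9-fold lower, and RBCS1A and LHCB1.3, which serve photosynthesis, were 2.60-fold and 3.06-fold lower with a Col mother.

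In all, 1298 of 16661 genes differed, 741 higher and 557 lower with a Col mother. PME5, a pectin methylesterase, had 219 ± 105 CPM with a Col mother and 0 reads with a Cvi mother, at least 5880-fold higher by the summed counts of each group (floor of 3 counts over the group without reads). MLP28 stood at 547 ± 309 and 0.253 ± 0.532 CPM, and BG3, a beta-glucanase, at 593 ± 128 and 2.34 ± 5.76 CPM. In the other direction scpl21 and ATGA2OX3, an enzyme that inactivates gibberellin, had 0 reads with a Col mother, at least 1506-fold and 1114-fold lower. GDH3, LCR36, MPC, LHT2 and DFD were also among the largest falls, with 88.4 ± 80.7, 58.5 ± 50.5, 44.4 ± 40.6, 39.6 ± 43.5 and 125 ± 79.98 CPM with a Cvi mother and at most 1.29 CPM with Col.

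By list, 9 of 24 measured G2 and mitosis genes were higher with a Col mother, 10 adjusted over the list alone. KN and the pair CDC20.1 (4.23-fold) and CDC20.2 (6.75-fold) led them. The list had camera adjusted p = 4.26e-11, and adjusted p = 0.0498 with an estimated correlation. FIE (2.78-fold) and CLF were the 2 of 8 Polycomb genes that were higher, 3 adjusted over the list alone (camera adjusted p = 0.00487, and 0.0230 as the adjusted p with an estimated correlation). Of 8 photosynthesis genes 5 were lower, the same number adjusted over the list alone (camera adjusted p = 6.26e-08, and adjusted p = 0.00632 with an estimated correlation). Of 11 known maternally expressed imprinted genes 3 were lower, FWA, HDG8 and MPC, with 5 adjusted over the list alone (camera adjusted p = 2.00e-06, and adjusted p = 0.00183 with an estimated correlation). Of 15 endosperm markers 4 were lower, and 6 were lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00099, and adjusted p = 0.0230 with an estimated correlation). HDG3 (3.26-fold) and PKR2 (3.55-fold) were the 2 of 7 paternally expressed imprinted genes that were lower, 3 adjusted over the list alone (camera adjusted p = 0.0354, but adjusted p = 0.322 with an estimated correlation). Of 11 type I MADS box genes 2 were lower in either adjustment, AT3G05860 and AT4G36590 (camera adjusted p = 0.0343, but adjusted p = 0.297 with an estimated correlation). Seed coat markers had a camera adjusted p of 0.310.

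The same class was held by different clusters in the crosses. Cluster 1 took 63.2% of the endosperm-like nuclei of Cvi x Col and 5.71% of those of Col x Cvi, while clusters 3 and 5 took 30.3% and 22.3% in Col x Cvi and 0.850% each in Cvi x Col. Most plates held 1 cross. With plate as a block on the 2 plates that hold both, 126 genes differed, 111 of them among the 1298, and AT4G36590 had a log2 fold change of 0.31. 594 genes differed on unwashed plates and 428 in 3C nuclei, with 576 and 379 of them among the 1298.

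Across these 1298 genes the fold between crosses went with the fold between days described below, where a Col mother matched the later day. Of these genes 1029 had the same sign in both (Spearman rho 0.701, Pearson r 0.651), against 8694 of 15341 genes that did not differ (rho 0.218). The correlation is across genes, which are not independent replicates. With plate as a block in the fit of the days rho was 0.637.

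**Figure D4:**
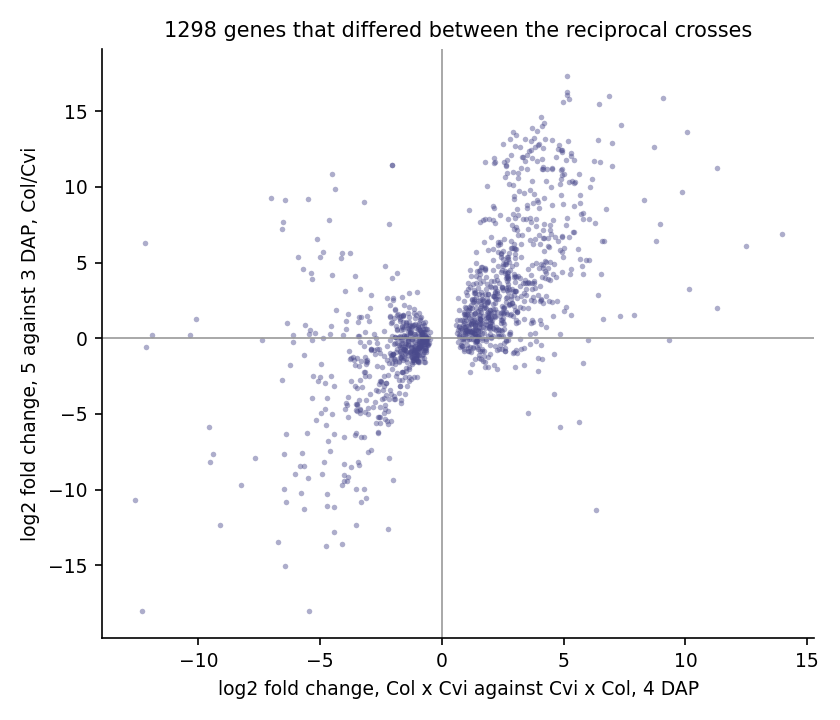
Fitted log2 fold change of Col x Cvi against Cvi x Col at 4 DAP (horizontal axis) and of 5 against 3 DAP in Col/Cvi (vertical axis) for each of the 1298 genes that differed between the crosses. 1029 points lie in the upper right or lower left part of the plot; fitted values beyond about 10 belong to genes with few or no reads in a group.

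Fewer genes differed between the reciprocal Col/Ler crosses, with 53 endosperm-like nuclei in 4 units against 43 in 3. Col x Ler had 1 unit of 3 DAP, 2 of 4 DAP and 1 of 5 DAP, and Ler x Col 2 of 4 DAP and 1 of 5 DAP. Day was a term of the model. The mean CPM with a Col mother include the unit of 3 DAP, which has no counterpart with a Ler mother, so they mix day and cross. Each unit of Ler x Col shared its plate and day with a unit of Col x Ler, a pairing the model did not use. AGO9, an argonaute protein, stood at 401 ± 265 CPM with a Col mother and 43.7 ± 60.8 CPM with a Ler mother, 9.38-fold higher (log2 3.23 ± 0.74 SE, adjusted p = 0.0257). It stood at 731 CPM in the unit of 3 DAP, and its adjusted p without that unit was 0.940. BG3 stood at 779 ± 411 and 159 ± 155 CPM. ICE1, a transcription factor needed for endosperm breakdown, stood at 752 ± 522 CPM with a Col mother and 2425 ± 219 CPM with a Ler mother, 2.48-fold lower (log2 -1.31 ± 0.25 SE, adjusted p = 0.00176). In the unit of 3 DAP ICE1 stood at 4.83 on the scale log2(CPM + 1), and at 9.72 in the nearest other unit with a Col mother. ACT9, SnRK1.3 and UBQ11 were higher and JMT was lower, and none of these 7 genes passed the threshold under all 14 alternatives. edgeR called 14 of 17591 genes, 8 higher and 6 lower, and 0 of 18 gene lists passed. 788 genes had an unadjusted p under 0.05 and DESeq2 called 273. Adding the nuclei of the cluster led by pollen genes left 1 gene, and clusters at resolution 2 or units of at least 10 nuclei left 0 in edgeR, with 699 and 511 genes at an unadjusted p under 0.05. Leaving out single units left between 1 and 12 genes, and without the unit of 3 DAP 0 were higher and 2 lower (751 at an unadjusted p under 0.05). Of the 1298 genes of the Cvi crosses 1259 were tested here, and 503 of them (40.0%) had the same direction (rho -0.259 across genes). Among 14441 genes that did not differ between the Cvi crosses, 6720 (46.5%) had the same direction (rho -0.0922).

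The days 3 and 5 DAP were compared within endosperm-like nuclei. In Col/Cvi both units of 3 DAP (19 nuclei) were on plate 7, which also held 2 of the 4 units of 5 DAP. In Col/Ler the single unit of 3 DAP (7 nuclei) was on plate 9 and both units of 5 DAP on plate 6, so day and plate cannot be separated there and no test of day is drawn from that pair. RGP4, a cell wall sugar mutase, stood at 383 ± 346 CPM at 5 DAP in Col/Cvi (SD, n = 4 units) with 0 reads in both units of 3 DAP, at least 336-fold higher. ROS1, a DNA demethylase, was at least 137-fold higher by a floor that covers counting error only. It was not past the threshold with plate as a block. LEC2, a regulator of seed development, stood at 106 ± 104 CPM at 5 DAP and 1.00 ± 1.42 CPM at 3 DAP in Col/Cvi.

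In Col/Cvi 370 of 19513 genes differed, 242 higher and 128 lower at 5 DAP. With plate as a block, a fit added after the data were seen, 63 differed, 49 higher and 14 lower, 47 of them among the 370, and 5 of the 24 genes named for Col/Cvi stayed past the threshold (RGP4, WRKY21, AACT1, HB-7 and BXL3). The balance in Col/Cvi depended on the setting, with 118 higher and 107 lower in classes from resolution 2, 253 and 200 with the nuclei of the cluster led by pollen genes, and 188 and 209 with all nuclei. The median gene itself had a log2 fold change of 0.45, so changes stand relative to that. WRKY21, AUX1, an auxin importer, and DRM2, a DNA methyltransferase, were at least 251-fold, 155-fold and 67.3-fold higher at 5 DAP in Col/Cvi. POK1, AACT1, HB-7, QWRF6, NF-YB6 and AILP1 had 0 reads at 3 DAP and between 47.0 and 145 CPM on average at 5 DAP. LHCB1.1 was 16.7-fold higher. Lower at 5 DAP were HDG10 and ARF22, at least 170-fold and 407-fold. scpl21 (262 ± 20.8 CPM at 3 DAP), BXL3 (389 ± 453 CPM) and XTH1 (165 ± 234 CPM) held 2, 1 and 1 reads at 5 DAP. TBL41, LpxA, GH9B17 and UMAMIT46 had 0 reads at 5 DAP. AGL62 fell at least 245-fold and ESF1.2, a micropylar peptide gene, at least 275-fold. The direction for AGL62 reversed without plate 7 Cvi x Col at 3 DAP (log2 0.16), and for UMAMIT46 (0.83), XTH1 (3.18) and GH9B17 (0.44) without plate 7 Col x Cvi at 3 DAP.

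In Col/Ler the levels are given without a test. KN and the kinesin gene HIK, both of cytokinesis, stood at 751 ± 206 and 122 ± 122 CPM in the 2 units of 5 DAP and at 8.58 and 0 CPM in the unit of 3 DAP. RGP4, ROS1 and ENODL4 stood at 393 ± 58.4, 217 ± 91.3 and 1140 ± 443 CPM at 5 DAP with 0 reads at 3 DAP. PGSIP3, ENODL14, FP3, AN3, JAZ12, UMAMIT25, sks17, NRPE1 and TPS2 likewise had 0 reads at 3 DAP, and NRPE1 had a log2 fold change of -0.27 when all nuclei were used. FWA stood at 1.68 ± 1.72 CPM at 5 DAP and 674 CPM at 3 DAP, AGO9 at 43.8 ± 57.4 and 731 CPM, CSP41A at 8.30 ± 11.1 and 694 CPM, and CAO at 3.46 ± 4.89 and 378 CPM. The fit fixed for this pair gave 178 of 17591 genes past the threshold, 169 higher and 9 lower at 5 DAP, a count that cannot be ascribed to the day.

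Endosperm markers fell in Col/Cvi, 1 of 18 over all genes and 5 adjusted over the list alone (camera adjusted p = 0.000562, and adjusted p = 0.0311 with an estimated correlation). So did known maternally expressed imprinted genes, 0 of 12 over all genes (4 at an unadjusted p under 0.05) and 3 adjusted over the list alone (camera adjusted p = 5.37e-05, and adjusted p = 0.00725 with an estimated correlation). With plate as a block these 2 lists had camera adjusted p of 0.0163 and 0.000902, but adjusted p = 0.214 for both with an estimated correlation. The paternally expressed and type I MADS box lists had camera adjusted p of 0.0161 and 0.0154 in the same direction, but adjusted p = 0.273 and 0.249 with an estimated correlation. With the nuclei of the cluster led by pollen genes 453 genes differed, with 214 of the 370 among them, and LEC2 and LHCB1.1 were no longer past the threshold.

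Among genes with parentally assigned reads in endosperm-like nuclei of Col/Cvi at 4 DAP, FIS2, a Polycomb gene silent in the paternal genome, was 99.9% maternal over 1406 reads (log2 ratio 7.35 ± 0.33 SE, 15 units, limma adjusted p = 5.08e-11). FWA was 99.2% maternal over 9009 reads and SDC, an F-box gene, 99.5% over 11059 reads. VIM5, of a family of methylcytosine-binding proteins, was 3.20% maternal over 1997 reads (log2 ratio -6.33 ± 0.51 SE, 16 units, limma adjusted p = 1.37e-09). PKR2, a chromatin remodeller, was 5.04% maternal over 3967 reads and BSU1, a phosphatase, 3.38% over 2778 reads.

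Of 10275 genes tested 1768 were biased to the mother and 86 to the father beyond 2 to 1. The strongest maternal calls included flavonoid and seed coat genes, namely BAN, LDOX, TT7 and GSTF12, with BAM5, GASA1, ADT4, PRP4, DELTA-VPE and MLP328, all of them over 98% maternal. Of 14 measured seed coat markers 13 were called maternal, in either adjustment. 73.5% of maternal calls were more abundant in seed coat-like than in endosperm-like nuclei, against 31.4% of paternal calls and 30.6% of uncalled genes. For such genes free seed coat RNA cannot be told apart from maternal bias in the endosperm. Among 2319 genes at least 2 times as abundant in endosperm-like nuclei, a limit set after this was seen, 90 were maternal and 35 paternal. The other leading paternal calls were VIM1 (13.0% maternal), DCL4, which makes small RNAs (17.5%), ULP1D (9.40%), DEL2 (10.5%), SMAP2 (15.2%), SK3 (24.1%) and the chromatin remodeller ATRX (15.6%). In Col/Ler, VIM1 had 59 maternal and 34 paternal reads in Col x Ler and 0 and 48 in Ler x Col. There its reads were mostly from Col in both directions. DCL4 and SMAP2 had more paternal than maternal reads in both. ULP1D, DEL2, SK3 and ATRX had too few reads in Ler x Col to compare. Of 13 measured DNA methylation genes 3 were paternal, in either adjustment.

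Of 12 known maternally expressed imprinted genes 6 were measured, and FIS2, FWA, SDC and HDG9 (90.14%) were called maternal. NRPD1 was called paternal, with 43.5% maternal reads and a departure of -1.60 ± 0.52 from 2 to 1 (limma adjusted p = 0.0371), and HDG8 was not called (departure 0.54 ± 0.53, limma adjusted p = 0.500). Of 11 known paternally expressed genes 4 were measured. VIM5 and PKR2 were called paternal and SUVH8 maternal (94.6%), with 3 paternal and 1 maternal adjusted over the list alone, where the same direction in both crosses was not asked for and HDG3 is the third. In Col/Ler, SUVH8 had 22 maternal and 0 paternal reads in Col x Ler and 0 maternal and 32 paternal reads in Ler x Col, so there all of its reads came from Col. Over all genes HDG3 was not called because its direction depended on the cross. Its log2 ratio was 1.25 with a Col mother and -2.52 with a Cvi mother (limma adjusted p = 0.00137 for the difference). BSU1 also differed between directions, -2.92 and -7.59 (limma adjusted p = 0.00774), and 597 genes differed in all.

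The median gene was 77.8% maternal, and with that gene as the reference 760 maternal and 228 paternal calls were made. In Col/Ler, 562 of the maternal and 19 of the paternal calls had at least 20 parental reads in each direction, and 359 and 15 of them departed the same way in both. Of 2438 uncalled genes 444 departed toward the father in both. Uncalled genes that departed toward the mother in both were not counted, so no background for the maternal calls is given. The median uncalled gene departed toward the mother, by 0.313 in Col x Ler and 0.329 in Ler x Col on the log2 scale.

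**Figure D5:**
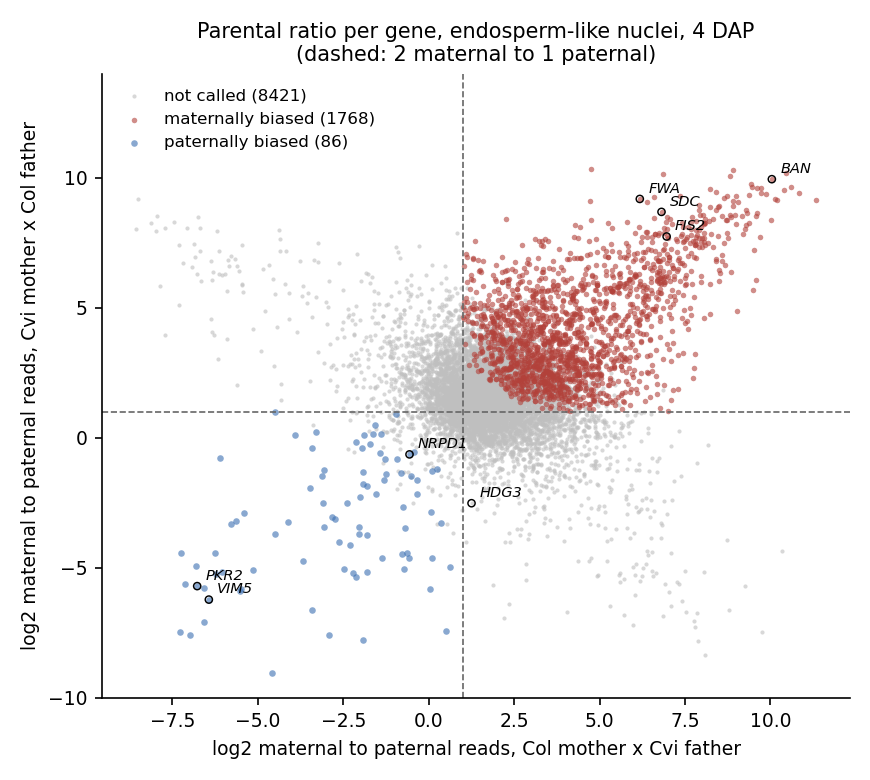
Log2 of maternal over paternal reads per gene with a Col mother (horizontal axis) and with a Cvi mother (vertical axis), in endosperm-like nuclei at 4 DAP, with dashed lines at 2 maternal to 1 paternal. The 1768 maternal calls lie upper right, the 86 paternal calls lower left, and HDG3 lies at 1.25 and -2.52.

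The parental ratio was also compared between chalazal-like cluster 16, 27 nuclei at 4 DAP in 11 units, and the other 729 endosperm-like nuclei. ACP2, an acyl carrier protein, had a log2 ratio of 6.04 over 503 reads in cluster 16 and 1.31 elsewhere, a difference of 4.73 ± 0.51 (limma adjusted p = 9.32e-07). ERD5, THI1, AGD2, MGL, SHM4, ARFA1E and CIPK15 were also more maternal there. In all, 132 of 1992 genes differed, 107 of them more maternal in cluster 16. Random sets of nuclei of the same number per plate and cross, a test added after the result, gave a median of 105 genes and as many as 132 in 10 of 51 sets, the real one included. The count thus did not exceed what small sets of nuclei give. Neither did the shift toward the mother, as the median difference over genes was 0.465 for cluster 16. In the random sets that value had a median of 0.604 (range 0.388 to 0.886). With 1 in place of 0.5 added to both read numbers, 96 genes differed, 61 more maternal and 35 less. For micropylar cluster 4, added after the data were seen, 6 of 5772 genes differed, 4 more maternal and 2 less. CGLD27 (difference -7.38 ± 1.18) and THA1 (3.85 ± 0.66), named after their values were seen, had the smallest p.

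Extra washing of nuclei, on 4 of the 12 large plates, was compared with 8 unwashed plates. A single gene differed between endosperm-like nuclei, AT5G60390, of a family of near-identical translation elongation factors, named here after its value was seen. It stood at 3738 ± 1143 CPM on 4 washed and 2075 ± 440 CPM on 8 unwashed plates (log2 0.82 ± 0.11 SE, edgeR adjusted p = 0.0337). 979 genes had an unadjusted p under 0.05, DESeq2 called 54 genes, and without each of 9 single plates in turn edgeR called 0. The share of seed coat-like nuclei was 29.1% ± 9.02 on washed and 32.4% ± 7.14 on unwashed plates (exact permutation test, p = 0.519). The list of sugar and amino acid transporters was higher on washed plates (9 measured, 0 of them over all genes, 2 at an unadjusted p under 0.05 and 1 adjusted over the list alone, camera adjusted p = 0.00015), but adjusted p = 0.0849 with an estimated correlation. Seed coat markers had a camera adjusted p of 0.0975.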

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

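The tests for strain bias of the maternal share, for the 10 genes that add most to it, and of genes against a null of up to 2-fold, were chosen only after the results were seen. Among 160 groups of 4 to 10 units, 29 held a unit far from the others, by its gap to the nearest unit over the range of the group. That is 18.1%, where chance gives about 1 in 20 groups for normal values. In 9 of the 29 only 1 unit had reads, which sets the share at 1, and the genes were picked for large folds, so the excess over chance is not read as a pattern. Values of genes are on the scale log2(CPM + 1), and each number is that gap as a share of the range.

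For Col x Cvi against Cvi x Col 20 of 69 groups had such a unit. With a Cvi mother, ACX6 and RABG3B on plate 22, PR5K on plate 11 and ROPGEF3 on plate 13 had reads on that plate alone, so the share was 1. The same holds with a Col mother for GDH3 and HMA3 on plate 20. With a Cvi mother the highest unit stood apart for AGP4 (0.895) and HDG8 (0.538) on plate 18, BG3 (0.755) on plate 19, HSP90.1 (0.564) on plate 8, and LrgB (0.541), MLP28 (0.659) and MPL1 (0.549) on plate 3. The lowest stood apart for AT4G36590 (0.669) on plate 3 and KN (0.608) on plate 11. With a Col mother the highest stood apart for LrgB (0.870) on plate 20 and LCR36 (0.566) on plate 8. The lowest stood apart for HSP90.1 (0.632), PKR2 (0.622) and RABG3B (0.543), all on plate 3.

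At 5 DAP in Col/Cvi BXL3, XTH1 and scpl21 had reads in 1 of 4 units, a share of 1 each. ICE1 was lowest in the unit of Col x Ler at 3 DAP on plate 9 (0.891). For the parental ratio the lowest unit stood apart for DEL2 (0.764) on plate 16 and LDOX (0.621) on plate 8 with a Col mother, and for FIS2 (0.616) on plate 3 and SK3 (0.622) on plate 18 with a Cvi mother. The highest stood apart for VIM5 (0.567) on plate 20 with a Col mother.

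A difference between the directions of the cross was found for the gain of endosperm-like nuclei from 3C to 6C (p = 0.0120), and for the maternal share (p = 0.00466), both by exact permutation tests.

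The maternal share of endosperm-like nuclei lay above 2 in 3 genomes. Assignment biased to 1 strain would lower the share in 1 direction, but the smaller of both means lay 4.92 standard deviations between plates above it, which argues against that as the whole cause. Free seed coat RNA may contribute, as seed coat markers had a median level in endosperm-like nuclei of 0.287 of that in seed coat-like nuclei (quartiles 0.164 and 0.478), where 0.238 is needed, although BAN (45.5%) and MYB5 (6.66%) are not in 1 ratio. Maternal expression of the 10 genes that add most to the excess is argued against as the whole cause, since without them the share was 72.8% ± 2.02, above 2 in 3 in 16 of 16 units. Without the 1768 genes called maternal, which held 23.5% of reads, it was 69.2% ± 1.91, above 2 in 3 in 15 of 16 units (exact sign-flip test, p = 9.16e-05), but these genes were picked by their share, so how far they carry it cannot be told apart, and maternal expression of many genes stays open.

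The genes that differ between Col x Cvi and Cvi x Col may reflect a difference in developmental stage, since their folds went with those of 5 against 3 DAP (rho 0.701, and 0.637 with plate as a block). The gene lists went with the days only in part. The 4 lists past the camera threshold for the days were also lower with a Col mother. The G2 and mitosis, photosynthesis and Polycomb lists differed between the crosses. For the days with plate as a block they had camera adjusted p = 0.883, 0.965 and 0.0999. The Polycomb list was higher with a Col mother but had a median log2 fold change of -0.986 in that fit. Seed coat RNA of the mother is argued against as the whole cause, as 19.5% of the genes were more abundant in seed coat-like nuclei. Of all genes tested 39.8% were. For the 253 genes that were more abundant there, it stays open. Strain differences in dosage or mapping of a gene expressed from both parents give at most 2-fold, so they are argued against as the cause for all of the genes, since 236 of the 1298 (18.18%) passed an edgeR test against a null of up to 2-fold. They cannot be told apart for the other 1062: 87.6% of all lay beyond 2-fold and 162 of 323 (50.2%) where a 2-fold change could be called, but the median smallest fold that could be called was a log2 of 1.60, so that test could hardly have come out otherwise, and its bound was set aside. Differences between the parents themselves were not tested.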

How the results depend on the processing

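The cause of the changes below was not tested. The cluster led by pollen genes, the micropylar cluster, the limit on abundance and plate as a block for the days were added after the data were seen. DESeq2 gave 264 genes for 6C against 3C, 2183 for Col x Cvi against Cvi x Col, 273 for Col x Ler against Ler x Col, 2798 and 1243 for 5 against 3 DAP in Col/Cvi and Col/Ler, and 54 for the wash. Without a count filter there were 648, 2119 and 663 genes for the peaks, the Cvi crosses and the days in Col/Cvi, and 53 for the wash. With plate and cross as a block 200 genes differed between the peaks. On the plates that hold both Cvi crosses 126 differed, on unwashed plates 594 and in 3C nuclei 428.

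For Col x Ler against Ler x Col all nuclei gave 1 gene, the added pollen cluster 1, and classes from resolution 2 and units of at least 10 nuclei 0 in edgeR (699 and 511 at an unadjusted p under 0.05). Single units left out gave 1 to 12 genes, with 6 without plate 6 Col x Ler at 5 DAP or plate 8 Col x Ler at 4 DAP, 5 without plate 6 Ler x Col at 5 DAP or plate 9 Ler x Col at 4 DAP, 2 without plate 9 Col x Ler at 3 DAP and 1 without plate 9 Col x Ler at 4 DAP. For the days resolution 2 gave 225 genes in Col/Cvi and 91 in Col/Ler, and units of at least 10 nuclei 223 in Col/Cvi and no value in Col/Ler. Plate as a block gave 63 in Col/Cvi. Leaving out either unit of 3 DAP left 1 unit at that day, and most of the 370 genes were then no longer past the threshold. Single units left out gave 256 to 497 genes in Col/Cvi where both units of 3 DAP stayed in. In Col/Ler they gave 99, without plate 6 Col x Ler at 5 DAP, to 289, without plate 9 Ler x Col at 4 DAP. For the wash edgeR gave 0 genes with RLE factors (968 at an unadjusted p under 0.05) and with all nuclei (967), and 0 to 2 without single plates, with 2 without plate 15 and 0 without any of plates 13, 14 and 16 to 22.

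Maternal and paternal calls were 1149 and 54 with at least 30 reads, 760 and 228 against the median gene, 1101 and 38 in 3C nuclei, 861 and 46 on unwashed plates, and 90 and 35 among genes at least 2 times as abundant in endosperm-like nuclei. All nuclei gave 5651 maternal and 6C nuclei 51 paternal calls. The micropylar cluster gave 6 genes. An estimated correlation kept 10 of 19 gene list calls.

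Directions reversed for AT4G36590 on the plates that hold both Cvi crosses (log2 0.31) and NRPE1 in Col/Ler with all nuclei (log2 fold change -0.27). At 5 against 3 DAP in Col/Cvi they reversed for UMAMIT46 (0.83), XTH1 (3.18) and GH9B17 (0.44), both in units of at least 10 nuclei and without plate 7 Col x Cvi at 3 DAP, and for AGL62 without plate 7 Cvi x Col at 3 DAP (0.16). The lowest log2 values without single units were -17.44 for UMAMIT46, -13.84 for XTH1, -14.95 for GH9B17 and -12.71 for AGL62, fitted values that depend on the prior count. Of the values of named genes under alternatives, 160 of 175 stayed past the threshold in the same direction for the peaks and 310 of 342 for the Cvi crosses. The numbers were 32 of 98 for the Ler crosses and 486 of 648 for the days in Col/Cvi. For parental ratios 350 of 360 kept their call or lack of a call. Some alternatives could not lose a call, which raises these numbers. They were units of at least 10 nuclei for the Cvi crosses, leaving out plate 1 for the days, and a departure of 0.5 for parental ratios. For the days in Col/Cvi 1 of 24 named genes stayed past the threshold under all 27 alternatives.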

Other observations

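The random sets of nuclei matched per plate and cross were chosen as a test only after the result was seen. Endosperm-like cluster 16 was led by ACT9, an actin gene, at 3252 CPM against 22.2 CPM in all other nuclei, and WRKY68, at 1151 against 3.26 CPM, as means over nuclei. Cluster 4 held ALE1, a protease gene of the endosperm near the embryo, at 680 against 19.8 CPM. Cluster 11 was led by CYCA3;1 and TK1a, found in 76.7% and 74.4% of its nuclei, and 2.33% of its nuclei came from the 6C peak, against 98.1% in cluster 7. These genes lead clusters that were made from the same counts, so no test is given.

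The maternal share of endosperm-like nuclei outside the main set, as values without a test, was 74.3% ± 1.57 in Col x Ler and 72.5% ± 0.353 in Ler x Col at 4 DAP (SD, 2 units each). At 5 DAP it was 73.7% ± 0.748 in Col x Cvi and 71.0% ± 0.148 in Cvi x Col (2 units each).

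For 6C against 3C 1 of 45 splits of the units gave as many genes, the real one with 116 (highest other 0). Among splits within plate and cross it was 1 of 45 (119 genes, highest other 0). Chance is thus unlikely for both, though 1 of 45 is the smallest share these splits can give. For Col x Cvi against Cvi x Col it was 1 of 80 (1298 genes, highest other 186), the smallest share possible, so chance is unlikely. For Col x Ler against Ler x Col 4 of 34 splits gave at least 14 genes (highest other 97), without keeping units of the same plate and day as pairs. For the wash 6 of 80 gave at least 1 (highest other 12). Chance cannot be excluded for these 2 comparisons. For the parental ratio in cluster 16, 1 of 100 splits of the units gave 132 genes (highest other 2), but 10 of 51 random sets of nuclei matched per plate and cross did (highest other 185), so chance among small sets of nuclei cannot be excluded.

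In nuclei of 3 DAP 6 pollen genes, listed after the leading genes were seen, took 0.428% of reads in the 25 nuclei of the unnamed cluster on plate 5, 0.121% in 13 on plate 1 and 0% in 3 on plate 7, against 0.371%, 0.0559% and 0.00125% in 9, 3 and 12 seed coat-like nuclei of these plates. Control wells had 688 of 11610 reads in these genes on plate 5 and 0 of 2346 on plate 7, and plate 1 had no such wells. On plates 3 and 19, both of 4 DAP, control wells had 111 of 1648 and 154 of 6399. Nuclei on plate 3 held 0.0197% (Col x Cvi) and 0.0353% (Cvi x Col) of reads in these genes, and on plate 19 0.000109%. Control wells therefore did not track the nuclei across plates. The median level in the seed coat-like nuclei of plates 1 and 5 was 0.959 of that in the cluster, so free pollen RNA on these 2 plates is a candidate explanation. Of 1715 parental reads of these genes in the cluster 59.6% were maternal, between the bounds set for transcripts of the pollen parent, which cannot be told apart by that value. Over all passing nuclei of plate 5 the reads were 80.5% Col in Col x Ler and 81.8% Col in Ler x Col, whichever parent was the mother. On plate 1 they were 83.5% Col in Col x Cvi. Where Col was the mother, these values argue against transcripts of the pollen parent as the main source. In Ler x Col, where Col was the father, the value cannot decide. No other biological explanation was tested.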
